A study of Mus musculus with 8 samples.

How the data were processed

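Gene expression was measured on Illumina MouseRef-8 v2.0 bead arrays, on which each probe is read as the average brightness of its beads. Per the labels, the 8 samples were 5 samples of neural stem cells (NSCs) derived from C57BL/6 mouse embryonic stem cells and kept with FGF2 and EGF, and 3 samples of their neuronal progeny. The progeny had spent 4 days in N2B27, a serum-free medium in which stem cells differentiate, were replated in Neurobasal with B27, and were sorted by flow cytometry on RedStar, a red fluorescent protein driven by the promoter of Tau (Mapt). Total RNA was amplified and labelled with biotin, per the labels' protocols. The groups follow the titles and cell type labels. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

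The authors deposited the average bead signal of every probe, an intensity on a linear scale that was neither background-subtracted nor scaled between arrays. Beside each signal the deposited table holds a detection score, a fraction from 0 to 1 that gives the share of negative control probes dimmer than the probe, so that 1 minus the score was used as the detection p. The authors also deposited processed log2 values, and the submitters' processing notes name limma without a version. Those log2 values equalled the quantile-normalized log2 signal without background correction, with a largest difference of 5.00e-09. Scanner software is not given in the sources used here. The medians of the authors' log2 values were 6.36 on every array.

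From the signals, neqc in limma 3.58.1 under R 4.3.3 fitted the background from the detection p, added an offset of 16, quantile normalized the 8 arrays and took log2. Quantile normalization sets every array to the same distribution, so each difference is relative to the other probes, and the offset shrinks the differences of dim genes. Probes with a detection p below 0.01 on at least 3 arrays were tested, which left 10499 of 25697. Of all probes, 23978 are paired with 1 gene in the platform table, 0 with several and 1719 with none, and 23962 were found by gene identifier in the reference gene table, which changed 0 symbols. A gene was represented by its tested probe with the highest mean over the 8 arrays, giving 7407 genes, 1856 of them with more than 1 tested probe and 33 with probes called in opposite directions. A linear model with group as its only term was fitted with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with 0.05 as the threshold. Differences are neuron minus NSC. All arrays were on 1 chip, with the stem cells at the first 5 positions and the neurons at the last 3, so position and group cannot be told apart. The culture conditions and the sorting named in the labels follow the group as well, so they cannot be told apart from cell type.

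A probe above background on at least 1 array of 1 group and on no array of the other has only a bound there. For such genes a fold is written as at least N-fold, computed from the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the probe's own value and the lowest value of any detected probe on that array.

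The 28 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added. The rule named the 5 largest rises and falls among called genes detected on all 8 arrays, the 5 brightest genes detected on all arrays of 1 group and none of the other, Mapt and Rest, and in each list the 2 called members that changed most in the majority direction with the 1 that changed most the other way, or both directions where they were equal. Nes, Sp8, Egfr, Id1, Sox2 and genes named for where they were detected were named outside the rule after their values were seen. So were the genes of the other observations that the rule does not name. Lists with at least 3 tested genes were tested with camera in limma, which asks whether the genes of a list rank higher or lower than other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment was over the 27 lists tested. A list's count is also given adjusted over the list alone.

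The alternatives were no background correction, normexp with an offset of 50, median scaling or cyclic loess in place of quantile normalization, the authors' values, other filters on dim probes, a trended robust variance, array weights, the mean of a gene's probes, the replicate number as a block and leaving out each array. Leaving out each neuron array with detection required on 2 arrays was added after seeing the data. The whole procedure was tested on simulated signals drawn from the real stem cell levels, in which 200 of 7471 tested genes were changed. It recovered 56.0% of genes changed 1.5-fold, 94.0% at 2-fold, 96.0% at 4-fold and 100% at 8-fold, and 5.98% of its calls were false. The simulated changes were split evenly between rises and falls, in genes detected on every NSC array. In the real data 64.6% of tested genes were called. Normalization with most genes changed, and recovery of genes not detected in NSCs, were therefore not tried. Of 4 simulated lists 1 was built from changed genes, and it alone was called, so list recovery was tried on 1 list only. Between 9369 and 10213 probes per array had a detection p below 0.01, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.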

Results

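The study set neural stem cells beside the early neurons made from them, to ask how gene expression differs between a cell with developmental potential and its differentiated progeny. Expression was read on 5 NSC arrays and 3 neuron arrays. The median signal of an array lay between 80.3 and 84.7, and 36.5% to 39.7% of probes were detected. Across probes, which are not independent replicates, log2 signals correlated at 0.993 to 0.994 within NSCs, 0.993 to 0.994 within neurons and 0.937 to 0.938 between the groups. The median SD of a gene within a group was 0.16 on the log2 scale in NSCs (n = 5) and 0.14 in neurons (n = 3).

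All 11 mitosis genes tested, of 17 with a probe, were lower in the sorted neurons. All 9 early neuronal differentiation factors tested, of 18 with a probe, were higher. In both lists some genes passed the filter through 1 group alone, so their direction was fixed. Prc1, which bundles microtubules at the end of mitosis, was at least 125-fold lower in neurons, and Mapt, which encodes the microtubule protein Tau, was at least 17.1-fold higher (log2 difference 4.64 on its brightest probe, and 2.99 with the mean of its tested probes). Of 7407 genes tested with limma, 2624 were higher in neurons and 2164 lower at an adjusted p below 0.05, in all 4788 genes or 64.6%. The fitted difference was at least 2-fold for 1661 of them, 786 higher and 875 lower, and at least 8-fold for 58 higher and 150 lower. With genes seen in 1 group alone set at their bound, 726 higher and 815 lower genes reached 2-fold, and 46 higher and 133 lower genes 8-fold. The arrays of the groups did not overlap for 4523 genes or 61.1%, where chance gives 3.57%. Of the changed genes 54.8% were higher, but 66.1% were with median scaling, which moved the median difference of all genes from 0.06 to 0.23, and 49.8% with cyclic loess. The fitted count at 2-fold depended on background correction and filter: it was 997 without background correction, 1047 with an offset of 50 and 1083 among genes detected on all 8 arrays. Sizes depended on it too: without background correction 28 of the 91 named genes and the medians of 5 of the 13 called lists moved by over 1.5 times, and with an offset of 50, 21 named genes and 3 called lists did.

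**Figure D1:**
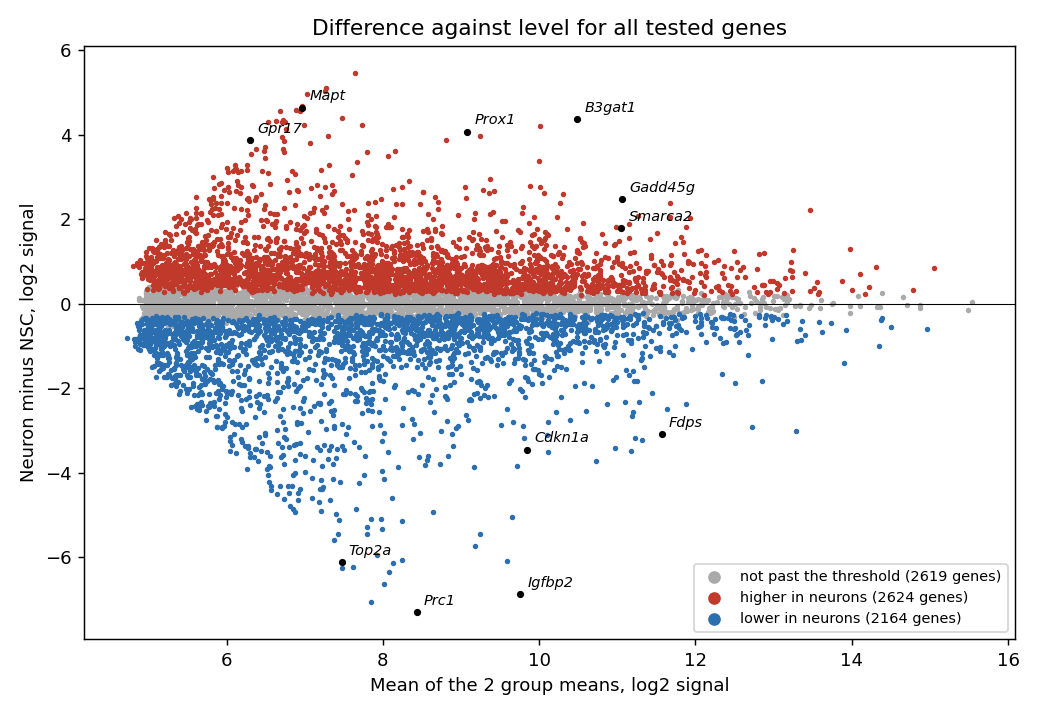
Each point is 1 of the 7407 tested genes, with the mean of the group means on the horizontal axis and neuron minus NSC on the vertical axis, both in log2 signal. Red points (2624) were higher in neurons and blue points (2164) lower at an adjusted p below 0.05, and the largest falls reach further from 0 than the largest rises.

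Among genes detected on all 8 arrays, the largest rises were those of B3gat1, Sdk1, Slc24a3, Prox1 and Myt1. B3gat1, an enzyme that builds the HNK-1 carbohydrate of neural adhesion molecules, went from 8.31 ± 0.12 (SD, n = 5) in NSCs to 12.67 ± 0.08 (n = 3) in neurons, a log2 difference of 4.37 (SE 0.10, limma adjusted p = 5.47e-11). The adhesion molecule Sdk1 rose by 4.23, the sodium/calcium exchanger Slc24a3 by 4.21, and the transcription factors Prox1 and Myt1 by 4.08 (2.48 with the mean of its probes) and 3.98. The largest falls were those of Igfbp2, a binding protein of insulin-like growth factors, Cenpa, the histone variant of centromeres, Ifitm2, Tead2 and Kif22. Igfbp2 went from 13.19 ± 0.07 (SD, n = 5) to 6.33 ± 0.37 (n = 3), a log2 difference of -6.86 (SE 0.15, limma adjusted p = 3.04e-11), and the other differences were -6.08 for Cenpa, -5.73 for Ifitm2, -5.43 for Tead2, a transcription factor of the Hippo pathway, and -5.33 for the mitotic kinesin Kif22.

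Detection on all neuron arrays and no NSC array was found for 252 genes, and the reverse for 252 others. The brightest of the neuron-only genes were Cbln1 (at least 24.8-fold higher), which organizes synapses, Pkd2l1 (at least 24.0-fold), Apcdd1 (at least 19.9-fold), Crmp1 (at least 17.4-fold, its fitted log2 difference being 4.69, or 2.97 with the mean of its probes), which acts in growth cone guidance, and the gap junction gene Gjd2 (at least 16.4-fold). The brightest NSC-only genes were, after Prc1, Pbk (at least 76.5-fold lower in neurons), Cdca3 (at least 74.2-fold), Tk1 (at least 48.9-fold, its fitted log2 difference being -6.22, or -3.94 with the mean of its probes), which salvages thymidine, and the kinesin Kif2c (at least 44.9-fold). The cells were sorted on the Mapt promoter, so the Mapt value reflects the gate. On its brightest probe Mapt read 4.65 ± 0.13 (SD, n = 5) in NSCs and 9.29 ± 0.03 (n = 3) in neurons. Of its 4 probes, 2 were detected on all neuron arrays and no NSC array, the dimmer at 4.37 in NSCs and 5.71 in neurons. The other two were detected on no neuron array, but 1 of them was on NSC 4, at 5.22. Rest, which represses neuronal genes in non-neuronal cells, has 1 probe, and it was not above background on any array.

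**Figure D2:**
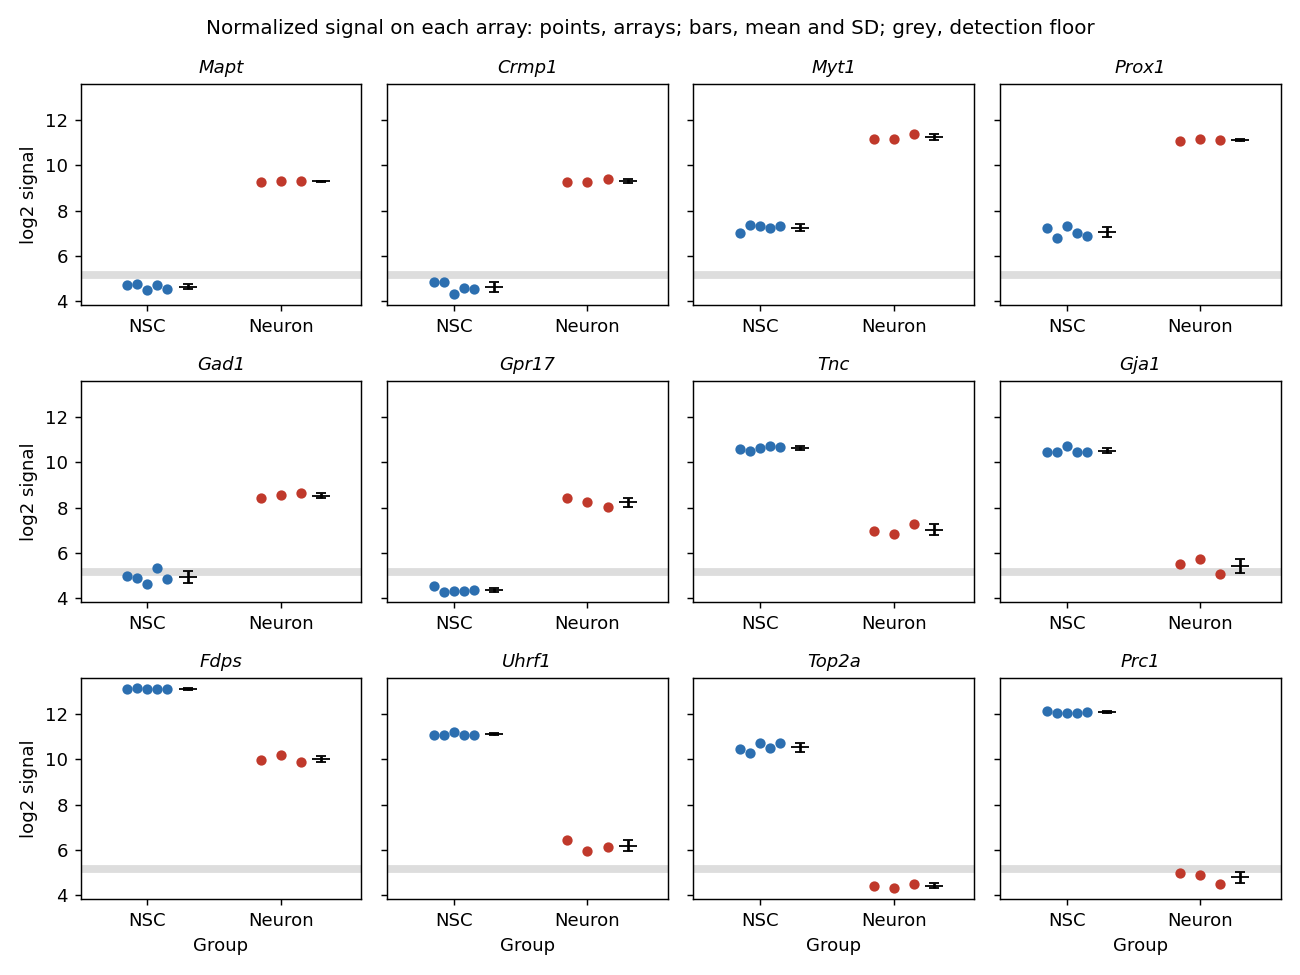
Normalized log2 signal of 12 genes on each array, with NSCs in blue (n = 5) and neurons in red (n = 3), the mean and SD beside the points and the range of the dimmest detected probes in grey. The 3 neuron arrays lie apart from the 5 NSC arrays in every panel, as for Mapt at 4.65 against 9.29 and Gja1 at 10.51 against 5.43.

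Neuronal groups were higher in neurons, and oligodendrocyte lineage markers (median 0.96) moved with them. All 9 tested early neuronal differentiation factors rose, among them Rbfox3, the NeuN antigen (at least 13.0-fold), and Myt1 (3.98). Of these, Dll3, Sox4, Rbfox3 and Celf4 passed the filter through the neuron arrays alone, so a fall could not have been seen. Of 13 genes of the neuronal cytoskeleton and growth cone 10 rose, including Crmp1 and Mapt, and 3 fell, led by the microtubule kinase gene Dclk1 at -2.12. Of 9 synaptic vesicle and presynaptic genes 7 rose and 2 did not pass, with Cplx1, a regulator of vesicle fusion, at least 12.3-fold higher and the vesicle protein gene Syn1 up by 2.11. All 9 tested REST target genes rose, Scg2 by at least 15.8-fold, but 5 of the 9 also stand in other lists. In the cytoskeleton list the probes of Mapt, Dcx, Stmn3, Gap43, Ina, Crmp1 and Kif5c also passed the filter through the neuron arrays alone. So did Cplx1 of the presynaptic genes, and Scg2, Cplx1, Stmn3 and Celsr3 of the REST targets. For these genes too a fall could not have been seen. Counts adjusted over the list alone were the same in these 4 lists, and in every list below unless another is given. The median log2 differences were 2.09, 1.64, 0.86 and 2.11, and became 1.68, 0.89, 0.86 and 2.11 with genes seen in 1 group alone set at their bound. Camera called each of the 4 (adjusted p = 0.000107, 0.00360, 0.00937 and 8.13e-06). None was called with an estimated correlation (adjusted p = 0.0522, 0.0641, 0.0641 and 0.0641 with an estimated correlation). The cytoskeleton call was also lost without Neuron 1, 2 or 3 (medians 0.30, 0.16 and 0.21, adjusted p = 0.688, 0.729 and 0.746) and with detection on all 8 arrays (median 0.20, adjusted p = 0.867), when the filter left 6 of the 13 genes. With detection required on 2 arrays, an alternative chosen after seeing the data, all 13 were tested and the call was kept.

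Other neuronal groups were mixed. Of 12 axon guidance and adhesion genes 8 rose, among them Celsr3 (at least 5.85-fold) and Cntn1 (2.65), 2 fell, led by the semaphorin receptor gene Plxna2 at -2.75, and 2 did not pass (list adjusted p = 0.133). Of 4 GABAergic genes, Gad1, which makes GABA, rose by 3.59 (2.28 without background correction) and was above background on only 1 NSC array. Calb2 was at least 1.77-fold higher, Dlx1 was at least 1.32-fold lower and Sp8 at 0.14 did not pass (list adjusted p = 0.457). Of 3 glutamatergic genes 2 rose, Neurog2 (at least 1.59-fold) and Rorb (0.48), and Slc17a8 fell, at -0.55 (-0.35 without Neuron 1), with a list adjusted p of 0.562. Of 4 voltage-gated channel genes 2 rose and 2 fell, the potassium channel genes Kcnd2 (2.92) and Kcnc1 (-2.56, or -1.67 with the mean of its probes) and the calcium channel subunit genes Cacnb4 (0.61) and Cacna2d1 (-0.31). Leaving out 1 array ended the calls of Cacnb4 (Neuron 1, 2 or 3, adjusted p = 0.0555 to 0.0681), Cacna2d1 (NSC 1, 2 or 4, Neuron 1 or 2, adjusted p = 0.0647 to 0.173) and Rorb (NSC 3 or 4, Neuron 1 or 3, adjusted p = 0.0539 to 0.144). So did the replicate block for Cacnb4 (0.46, adjusted p = 0.0741) and Cacna2d1 (-0.29, adjusted p = 0.138), median scaling for Cacna2d1 (-0.0851, adjusted p = 0.517), cyclic loess for Rorb (0.38, adjusted p = 0.0742), and no filter for all of them (adjusted p = 0.0530, 0.0601 and 0.0736). The channel list's test pointed down (adjusted p = 0.962) while its mean was 0.17 and its median 0.15, or 0.0923 without Neuron 3, 0.230 without NSC 1 and -0.31 with detection on all 8 arrays.

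The groups of dividing cells fell together. All 11 tested mitosis genes were lower, by a median of -5.29, with Cdc20, an activator of the anaphase-promoting complex, at least 70.9-fold and Top2a, the topoisomerase of dividing cells, at least 42.7-fold lower. All 19 tested DNA replication genes were lower, by a median of -3.21. Among them were Tk1 (at least 48.9-fold) and the chromatin assembly gene Chaf1b (-4.16, its probe being above background on only 1 neuron array). Set at their bounds the medians were -5.13 and -2.84. Among the mitosis genes the probes of Top2a and Cdc20 passed the filter through the NSC arrays alone. Among the replication genes so did those of Mcm3, Mcm7, Pcna, Cdc6, Rrm2, Pole and Tk1. For these genes a rise could not have been seen. Camera called both lists (adjusted p = 5.55e-10 and 1.03e-11), and these were the only lists called with an estimated correlation as well (adjusted p = 0.00740 and 0.00588). Genes of cell cycle exit did not rise as a group. Of 9, 6 fell, including the inhibitors of cyclin-dependent kinases Cdkn1a (-3.45) and Cdkn2c (-2.06, or -0.63 with the mean of its probes), and 3 rose, led by the stress and differentiation gene Gadd45g (2.48), with a list adjusted p of 0.278.

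Stem cell and growth factor genes were lower, with exceptions. Of 16 NSC and radial glia markers 10 fell, including the matrix protein gene Tnc (-3.59, or -2.20 with the mean of its probes) and the hyaluronan receptor gene Cd44 (at least 8.92-fold), and 4 rose, led by Id4 (at least 1.87-fold), or 5 adjusted over the list alone. The other called risers were Egfr (0.61), Id1 (0.51) and Sox2 (0.37). Nes, the stem cell filament gene nestin, did not pass at -0.16. Sox1, Pax6, Nr2e1, Msi1, Prom1 and Gli3 were above background on no array of either group. Of 13 feedback genes of FGF and EGF signalling 9 fell, with Ier3 at least 14.7-fold lower and the transcription factor gene Etv4 at -4.05, 2 rose, led by Egr1 (0.78), and 2 did not pass. The medians were -0.71 and -1.22, or -0.51 and -0.86 with bounds (camera adjusted p = 0.0325 and 0.00102). With an estimated correlation neither was called (adjusted p = 0.0886 and 0.0641 with an estimated correlation). Of 15 pluripotency markers with a probe 4 were tested, and the others, Pou5f1, Nanog and Zfp42 among them, were above background on no array of either group. Of the 4, 3 fell, led by Esrrb (at least 2.45-fold) and Klf2 (-0.89), and the list did not pass (adjusted p = 0.0795, or 0.0492 without NSC 1 and 0.0476 with median scaling). Of the mesenchymal and endoderm markers only Acta2 was tested, at -0.62, and the list had too few genes for a test.

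Glial markers moved in opposite directions. Of 10 tested astrocyte markers 7 fell, or 8 adjusted over the list alone, 2 rose and 1 did not pass. Gfap, Aqp4, Apoe, Glul and Mlc1 were above background on no array, and S100b on too few to be tested. The gap junction gene Gja1 fell by 5.08 on the log2 scale and Acsbg1 was at least 23.2-fold lower, while the neurotensin receptor gene Ntsr2 rose by 3.29. Of 9 oligodendrocyte lineage markers 7 rose, with Gpr17, a receptor of precursors committed to differentiate, at least 8.25-fold and Fa2h, an enzyme of myelin lipids, at least 4.81-fold higher, Opalin fell by 0.77 on the log2 scale and 1 did not pass. The medians were -0.93 and 0.96, or -0.93 and 0.85 with bounds (camera adjusted p = 0.0138 and 0.0103). Neither was called with an estimated correlation (adjusted p = 0.0677 and 0.0641 with an estimated correlation). The oligodendrocyte call was lost without Neuron 1, 2 or 3 (medians 0.53, 0.55 and 0.48, adjusted p = 0.275, 0.281 and 0.368), when 5 of the 9 genes passed the filter, and kept with detection required on 2 arrays. With detection on all 8 arrays neither list was called, with medians of -0.0254 for astrocyte and 0.51 for oligodendrocyte markers (adjusted p = 0.867 and 0.431).

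Metabolic groups fell. Of 14 cholesterol biosynthesis genes 13 fell and 0 rose, among them Fdps (-3.09), which makes farnesyl pyrophosphate, and Lss (-2.52), which closes the sterol rings. Of 10 glycolysis and hypoxia genes 7 fell, led by Hk2 (-2.88) and the glucose transporter gene Slc2a1 (-2.86), 1, Pgk1, rose by 0.43 on a dim probe, and 2 did not pass. Of 10 housekeeping genes used as controls 6 fell, led by Gusb (-2.13) and Rpl13a (-1.79), Pgk1 rose and 3 did not pass. The Pgk1 call was lost without NSC 1, 2, 3 or 5 or Neuron 2 or 3 (adjusted p = 0.0520 to 0.157), without background correction or with the authors' values (0.18, adjusted p = 0.0753), with an offset of 50 (0.19, adjusted p = 0.0684) and with no filter (adjusted p = 0.0675). The medians were -2.07, -0.85 and -0.50 (camera adjusted p = 2.89e-06, 0.00470 and 0.0477). None was called with an estimated correlation (adjusted p = 0.0641, 0.0641 and 0.115 with an estimated correlation). The housekeeping call was also lost without NSC 3 (0.0597), NSC 4 (0.0588), Neuron 1 (0.0800), Neuron 2 (0.0696) or Neuron 3 (0.0572), and with cyclic loess (0.0690) or the replicate block (0.0502).

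Chromatin regulators changed gene by gene. Of 8 genes of DNA methylation 4 fell, including Uhrf1 (-4.92), which brings the maintenance methyltransferase to replicated DNA, and that enzyme's gene Dnmt1 (-1.44), Mbd1 rose by 0.44 (0.20 with the mean of its probes, not called, adjusted p = 0.101) and 3 did not pass (adjusted p = 0.0720, or 0.0391 with no filter). Of 14 Polycomb genes 6 rose, led by Ring1 (0.59) and Mtf2 (0.53), 2 fell, led by the methyltransferase gene Ezh2 (-0.77), and 6 did not pass (adjusted p = 0.576). The Mtf2 call was lost without NSC 5, Neuron 1 or Neuron 3 (adjusted p = 0.0598 to 0.114), with cyclic loess (0.42, adjusted p = 0.0704) and with no filter (adjusted p = 0.0676). Of 15 histone methyltransferases and demethylases 7 rose, led by Smyd3 (1.40) and Kdm5b (1.19), 2 fell, led by Kmt5a (-1.36), and 6 did not pass (adjusted p = 0.278). Smyd3 was above background on only 2 NSC arrays and Kdm5b on only 1, and without background correction their rises were 0.70 and 0.54. Of 17 histone acetylation genes 8 rose, or 7 adjusted over the list alone, led by Sirt1 (0.98) and Hdac5 (0.92), 2 fell, led by Hdac1 (-0.59, or -0.37 with median scaling), and 7 did not pass (adjusted p = 0.457). Of 12 BAF remodelling subunits 6 rose, led by Smarca2 (1.79) and Smarcc2 (1.78), Dpf1 fell at -0.39 and 5 did not pass (adjusted p = 0.0723, or 0.0356 without Neuron 1 and 0.0362 without Neuron 3). The Dpf1 call was lost without NSC 1 or 2 or any 1 neuron array (adjusted p = 0.0540 to 0.123), without background correction or with the authors' values (-0.16, adjusted p = 0.0972), with an offset of 50 (-0.18, adjusted p = 0.0887), median scaling (-0.32, adjusted p = 0.0662), a trended robust variance (adjusted p = 0.0564) and no filter (adjusted p = 0.0709). Of 10 REST corepressor genes 4 rose, led by Rcor2 (0.93) and Ctdsp2 (0.87), 4 fell, led by Hmg20b (-1.57) and Hdac1 (-0.59), and 2 did not pass (adjusted p = 0.796), with a mean of -0.03 and a median of 0.01 (-0.0547 to 0.0936 without 1 array). Of 8 patterning homeobox genes 4 fell, led by Otx1 (-2.16) and Hoxa5 (-1.06), 2 rose, led by En2 (0.79), and 2 did not pass (adjusted p = 0.457). Of 8 dissociation and stress genes Jun (1.21) and Ddit3 (1.11) rose, Fos fell by 0.64 on the log2 scale and 5 did not pass (adjusted p = 0.788).

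**Figure D3:**
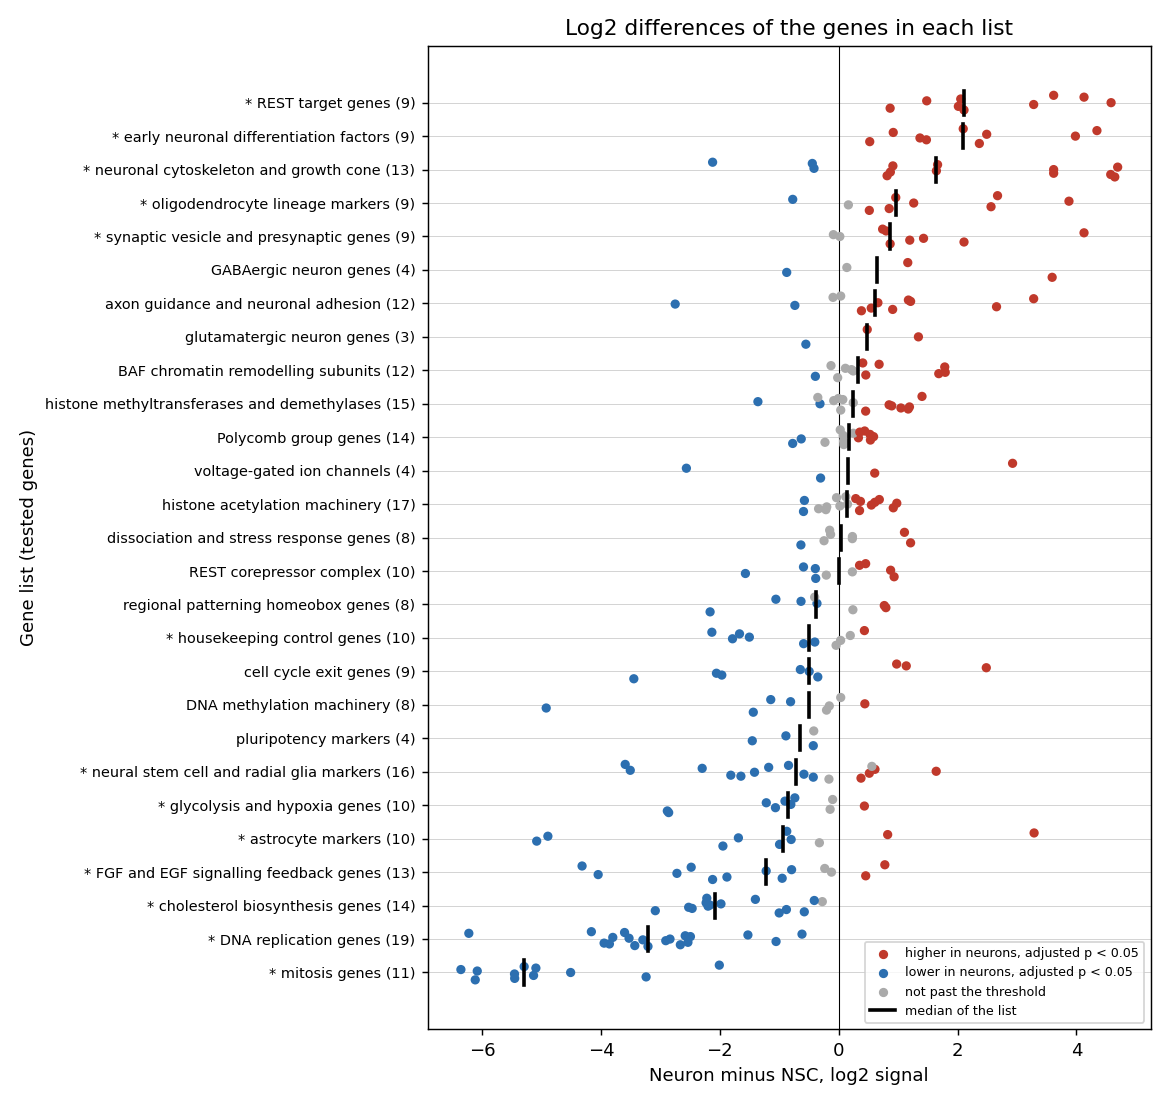
Each point is a tested gene of a list, placed by its neuron minus NSC difference in log2 signal, red where higher and blue where lower at an adjusted p below 0.05 and grey otherwise, with the list's median as a black bar and a star where camera called the list. Of 27 lists 13 were called, 5 higher and 8 lower, from REST target genes at a median of 2.11 (adjusted p = 0.0641 with an estimated correlation) to mitosis genes at -5.29. Only the mitosis and DNA replication lists, 2 of the 13, were called with an estimated correlation too.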

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

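None of the tests in this part was chosen after its result was seen. Among the 5 NSC arrays, 14 of 123 sets of values (genes, list means and array summaries) held 1 array far from the other 4, where chance gives about 1 in 20. NSC 3 stood apart for 6 of them. It read higher for Cd44 (8.46, the others 8.19 to 8.26), Gja1 (10.71, the others 10.44 to 10.48), Esrrb (6.67, the others 6.29 to 6.39), Etv4 (9.93, the others 9.72 to 9.76) and Uhrf1 (11.20, the others 11.07 to 11.09), and lower for Lss (8.15, the others 8.65 to 8.78). NSC 2 read lower for Dnmt1 (7.98, the others 8.80 to 8.96) and for the mean of the DNA methylation list (9.05, the others 9.17 to 9.21), and higher for Fdps (13.16, the others 13.09 to 13.10). NSC 1 read higher for Ifitm2 (12.28, the others 11.95 to 12.03) and lower for Klf2 (5.57, the others 5.86 to 5.94). NSC 5 read higher for the mean of the mitosis genes (10.07, the others 9.94 to 9.97) and of the early neuronal differentiation factors (6.41, the others 6.26 to 6.29), and NSC 4 for the mean of the histone acetylation genes (7.99, the others 7.87 to 7.90).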

How the results depend on the processing

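The added alternative, leaving out each neuron array with detection required on 2 arrays, was chosen after seeing the data. The count of changed genes, 4788, lay between 3796 and 4990 over the alternatives. Genes at 2-fold by the fit fell from 1661 to 997 without background correction, 997 with the authors' values, which are the same normalization, 1047 with an offset of 50 and 1083 with detection on all 8 arrays, which tests fewer genes; for the others the cause was not tested. Of 27 lists tested, 13 were called, 2 with an estimated correlation and 24 by fry, which asks whether a list moves, on balance, 1 way. No named gene turned direction where tested. Of 91 named genes 53 were tested under all 23 alternatives, and 49 of these kept their call. The other 38 had no value with detection on all 8 arrays, 15 of them none without 1 or more of the neuron arrays either, and 35 kept their call where tested. Cacnb4, Cacna2d1, Rorb, Mtf2, Mbd1, Dpf1 and Pgk1 lost it in 60 of 2010 pairs of gene and alternative. Differences of 8 named genes moved by over 1.5 times with the mean of a gene's probes (Prox1, Crmp1, Tk1, Mapt, Tnc, Kcnc1, Cdkn2c and Mbd1) and of 2 with median scaling (Cacna2d1 and Hdac1), and the medians of 7 called lists with no filter and of 4 with detection on all 8 arrays. Of 27 lists 3 had too few genes under some alternatives, and of the 613 pairs of list and alternative tested, 17 lost a call, 5 gained one and 18 turned the sign of a median, all in lists that were not called. The REST corepressor median, 0.01, was -0.0211 without background correction and with the authors' values, -0.0182 with an offset of 50, -0.0436 with cyclic loess, -0.0484 with the mean of a gene's probes, and -0.0547 to 0.0936 without 1 array, where with detection on 2 arrays it was -0.0547 without Neuron 2 and -0.0128 without Neuron 3. The stress median, 0.05, was -0.0254 with cyclic loess, -0.14 with detection on all 8 arrays, -0.0513 with the replicate block and -0.0306 to 0.198 without 1 array, negative without Neuron 3. The channel median was -0.31 with detection on all 8 arrays and the glutamatergic median -0.0230 with no filter. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.0169, 0.0138 and 0.0146, within the -0.0362 to 0.0367 of all cross pairs. With the number as a replicate block 4332 genes were called, 4208 of them shared, and 12 lists. Dim genes are limited by signal over background, and only a bound is known for those seen in 1 group.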

Other observations

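The gene family search, the comparison of undetected genes, the astrocyte test and the tests of a step in brightness and in particular probes, and the ribosomal tests without Rpl13a and Rplp0, were chosen after results were seen, and the oligodendrocyte and ribosomal patterns were noticed in the data. The requirements that a test hold without each array, and that markers not already be bright in stem cells, were also applied after the values were seen.

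Of 113 families formed by symbol, camera called 2 as higher in neurons, clustered protocadherins and zinc finger genes, and neither with an estimated correlation. Of 8 Pcdhb genes, which encode adhesion molecules that give neurons distinct surface identities, 7 rose, among them Pcdhb3 (3.36) and Pcdhb7 (3.06), with a median of 1.91 (adjusted p = 0.0148, and adjusted p = 0.457 with an estimated correlation). Of 150 Zfp genes 90 rose, 8 fell and 52 did not pass, with a median of 0.50 (adjusted p = 0.000457, and adjusted p = 0.405 with an estimated correlation). Both medians stayed above that of all genes under 3 scalings and 2 other background corrections, by at least 0.98 and 0.27. Of 10 tested genes of another neuronal list, written before its values were seen but for Cdk5r1, which was left out, 7 rose, led by Nsg2 (3.98), 2 fell, led by Camk2b (-2.75), and the median was 1.36 (adjusted p = 0.0339, and adjusted p = 0.194 with an estimated correlation).

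Several textbook neuronal genes, among them Tubb3, Stmn2, Snap25, Syt1 and Nefl, were not above background on enough arrays to be tested. Of 37 genes of the cytoskeleton and presynaptic lists with a probe, 15 (40.5%) were not tested, against 9 of 39 (23.1%) in the replication and mitosis lists, Ccna2, Bub1 and Ttk among them (Fisher's exact test, 2-sided p = 0.139). The test does not show whether the shares are alike, and no cause was tested.

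Oligodendrocyte lineage genes were higher in the sorted neurons, with a median of 0.96, but 5 of the 9 tested, with Olig1 brightest at 13.30 in NSCs, were above background on all NSC arrays too, and Mbp, Mog, Mag and Mobp were on none of the 8 arrays. As given above, the camera call of the list was lost with an estimated correlation (adjusted p = 0.0641). It was also lost without any 1 neuron array, unless detection was required on 2 arrays only. The median was 1.06 with median scaling and 0.94 with cyclic loess. It stayed at least 0.74 above that of all genes under these, quantile normalization and 2 other background corrections. But Pdgfra, Gpr17, Ugt8a and Fa2h passed the filter through the neuron arrays alone, so a fall of these could not have been seen. The 5 genes detected on all 8 arrays had a median of 0.51 (camera adjusted p = 0.431), and the scalings were not run on them alone. Whether scaling between arrays accounts for the rise is therefore not decided. Another list of oligodendrocyte precursor genes, without Omg, whose rise had been seen, had 4 of 7 tested genes higher, led by Lims2 (3.66), 1 lower, Itpr2 (-0.66), 2 that did not pass, and a median of 0.31 (adjusted p = 0.156), so cells or transcripts of that lineage passing the Tau gate may or may not contribute. A loss of stem cell transcripts that raises all other cell types alike stays open too: the astrocyte median was -0.93 (bootstrap SE 0.67), but 8 of the 10 tested markers were above background on all NSC arrays, which would hide a small share. Expression of these genes by the neurons themselves is a further hypothesis that was not tested.

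Of 52 ribosomal protein genes 22 fell and 5 rose in neurons, with a median of -0.19, a pattern looked for after Rpl13a and Rplp0 were seen to fall. Without these, 20 of 50 fell, 5 rose and 25 did not pass, with a median of -0.15. Scaling could account for part of it: relative to all genes the median was -0.19 to -0.46 over 3 scalings and 2 other background corrections, and -0.15 to -0.46 without the genes that prompted the search, never reaching 0 but not always below the bound of -0.3 set beforehand. Compression of bright signals on the neuron arrays was tested with 10000 lists of other genes at the same level, of which 1.92% had a median as low (1.02% to 2.65% without 1 array), but 3.38% without the genes that prompted the search (1.73% to 5.07% without 1 array). These shares lie on both sides of the bound set beforehand, so compression cannot be told apart from a change in the cells.

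That these arrays fell into such groups by chance is argued against for the large number of genes past the threshold. Of the 56 splits of the arrays into 5 and 3, only the real 1 gave as many changed genes (4788, the highest other 0), as many higher (2624, the highest other 0), lower (2164, the highest other 0) or genes changed 2-fold by the fit (1661, the highest other 0). Every other split mixes the groups, which puts their difference into the spread, so the counts of 0 add nothing beyond 1 split in 56. A chance difference between cultures cannot be excluded, since the replicates may be technical. For lists called, 2 of the 56 splits gave as many, the real value being 13 and the highest other 13, in a split that set NSC 1, 3 and 4 apart from all other arrays and called 0 genes. The 10 splits that set 3 NSC arrays apart called 7 to 13 lists, the 15 that set 1 NSC and 2 neuron arrays apart 5 to 10, and the 30 others 0 or 1. The first 2 kinds keep part of the real group difference, while the 30 others hold neurons in nearly equal shares on both sides. List counts of the other splits therefore do not measure chance. Linear drift along the chip is argued against, at 0.00969% of the variance of the differences (-0.515% to 0.515% over the 120 orders of the NSC arrays). Also argued against is a step in brightness between the groups' positions that varies with signal level. With median scaling, level accounted for 0.548% of that variance (0.492% to 0.643% without 1 array). The test could not show a step common to all probes, since the scaling removes it. A step in particular probes that took no account of what their genes do is argued against for the mitosis and DNA replication genes, whose lists stood apart from other genes (camera adjusted p at most 0.00740 with an estimated correlation, and 0.0129 to 0.0215 without 1 array). These lists were chosen after they alone had been called with an estimated correlation, so apart from leaving out arrays the test repeats that call. For other genes such a step cannot be told apart from the groups, since the groups do not share positions, and the biological difference that the design names stays open, as untested. Culture conditions and sorting, which also follow the groups, were not tested and cannot be told apart from cell type.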
